A study of Mus musculus with 30 samples.

How the data were processed

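The RNA libraries came from Six2-positive cap mesenchyme of mice on a mixed 129 and C57BL/6 background, with 1 library per group: E16.5 control, Ezh2-null, Ezh1-het Ezh2-null, Ezh1-null Ezh2-null (double-null) and P2 control. Libraries were made with 10x Genomics version 2 chemistry and sequenced on a NextSeq500, per the labels. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger 2.1.0 and analysed with Seurat 3.1.2. The deposited matrices hold whole-number UMI counts per gene and barcode, with no normalization. The E16.5 matrices list 27998 genes and the P2 matrix 31053, so the P2 library was counted on another annotation. Identifiers present in all matrices numbered 27514, of which 1027 carried another symbol at P2 and 25 symbols were duplicated. The E16.5 symbols were used, and CPM (counts scaled to 1 common total per library) were taken over the shared genes. The 25 chromatin accessibility libraries were not analysed here.

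Cells were kept with at least 500 detected genes, at least 1000 UMIs and under 10% of UMIs from mitochondrial genes. Scrublet, called through scanpy 1.11.5 with an expected rate of 0.06 and its automatic threshold, marked 0% to 0.275% of cells per library and so had not worked. The 5% of cells with the highest scores were removed from each library instead, as laid down beforehand. All 5 libraries were clustered together on 2000 variable genes chosen within libraries, leaving out mitochondrial, ribosomal, sex-linked and cell cycle list genes and Ezh1 and Ezh2, with 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9) and no batch integration. The random seed was 0. An approximate neighbour search was replaced by an exact one, so that repeat runs gave identical clusters, after the first clusters had been seen.

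Clusters were named from markers of 11 cell classes fixed before the data were examined: nephron progenitor, committing nephron, podocyte, proximal tubule, loop and distal tubule, ureteric epithelium, stroma, endothelium, immune, erythroid and neural. The scoring was set after the clusters were seen. Each cluster took the class whose markers, as a share of their level in the highest cluster, had the highest mean, over markers reaching 50 CPM in some cluster and for classes with at least 3 such markers. A cluster stayed unnamed when another class had more markers than its own among its 10 leading genes by fold (with 10 CPM added, averaged over libraries with at least 20 of its cells). Classes other than nephron progenitor also needed at least 2 own markers there. This rule left clusters 5, 7, 9, 12 and 16 unnamed, and the progenitor-like shares, ratios of named genes, list medians, counts of regulators and cycling shares were also computed with clusters 5, 7, 9 and 16 added to the progenitor-like class. Only 7 P2 cells were progenitor-like in the joint clustering, so the P2 comparison used cells named in clusters made within each library. That step departs from the plan and was chosen after the data were seen. A P2 cluster of 553 cycling cells with Six2 among its leading genes stayed unnamed there, and the P2 values were also computed with it added.

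Raw counts were summed over the progenitor-like cells of each library and compared as log2((CPM + 5)/(CPM + 5)), which understates the change of genes with low counts. Sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals, at 95%, for counting error only. Ratios against 0 counts were computed over a floor of 3 counts in that library and are given as lower bounds. With 1 library per group no p-value, standard error or number of changed genes was derived. Over 7 comparisons, each of the 3 mutants and P2 was set against the E16.5 control, and the Ezh2-null, het and double-null libraries were set against each other for Ezh1 dose. For named genes, the median distance from the log2 ratio to the edge of its interval lay between 0.0925 and 0.167 per comparison.

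The 15 gene lists were fixed beforehand: PRC2 subunits, developmental regulators of other lineages, Hox groups 1 to 9, Hox groups 10 to 13, cyclin-dependent kinase inhibitors, Wnt target, Notch pathway and p53 target genes, S phase, G2 and M phase, glycolysis, oxidative phosphorylation, heterochronic genes, imprinted genes and dissociation stress. Members with at least 10 counts over the libraries compared were measured, members at least 1.5-fold higher or lower were counted as a size, and the median was ranked among 10000 random lists of the same size matched on expression. Chance for genes in the same direction in all 3 mutants was taken from 1000 Poisson draws of unchanged libraries and from the product of the 3 shares, both set after the data were seen. Named genes were chosen by a rule set beforehand, among genes at 20 CPM or more in 1 of the libraries compared, leaving out mitochondrial, ribosomal, haemoglobin, sex-linked and unnamed gene models. They were the 10 highest and 10 lowest ratios per comparison with the control, the 10 genes with the largest smallest ratio above and below it in all 3 mutants, and the 5 up and 5 down with the largest total change over Ezh1 dose with steps of at least 0.3. To these were added Ezh1, Ezh2, Eed, Suz12, Six2 and Cited1, and up to 4 members per list and comparison with the largest ratio. Cell class markers, and the regulators given with their counts beyond these, were named after their values were seen.

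The cycling share is the share of cells with a UMI of Mki67 or Top2a after each cell was thinned to 2000 UMIs, leaving out shallower cells. Alternatives were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors (R 4.3.3), pseudocounts of 1 and 20 CPM, no low-count filter, all filtered cells, thinning to 2000 or 4000 UMIs, each library's full gene set, doublets kept, no cell filter (with doublets removed or kept) or a stricter one (1500 genes, 5% mitochondrial), resolutions of 0.5 and 2, and clustering within libraries. The ratio and list steps were tested on simulated data drawn from the real sums, with 200 genes changed by folds of 1.5, 2 and 4 up or down. Every changed gene of each fold size had the right direction in the simulated Ezh2-null (14296 genes), het (13975), double-null (14472) and P2 (13941) comparisons with the control. Over the fold sizes, the intervals held the true value for 91.2% to 100% of genes in the simulated Ezh2-null and double-null comparisons, for 88.2% to 97.0% in the het and for 88.2% to 97.1% in the P2 comparison. A list raised 1.5-fold came out at percentile 100 in each. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene positions are those of mm10.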

Results

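The series covers Six2-positive cap mesenchyme, the nephron progenitor population of the mouse kidney, from animals carrying mutations of Ezh1 and Ezh2. These genes encode the alternative histone methyltransferases of Polycomb repressive complex 2 (PRC2). The labels tie the Six2 Cre transgene to the Ezh2 mutation only, so Ezh1 may be lost in every cell type of its mutants. Of the 30 libraries in the series, 25 profile chromatin accessibility and were not analysed here, and 5 are droplet single-cell RNA libraries. The RNA groups were an E16.5 control carrying the Six2 Cre transgene, an Ezh2-null, an Ezh1-het Ezh2-null and an Ezh1-null Ezh2-null (double-null) library, all at E16.5, and a P2 control. Each group held 1 library, so no difference below has a replicate check and no significance test was made. Intervals are 95% intervals for counting error only, except those marked as over genes, which come from resampling the genes chosen.

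The control library held 10524 barcodes with 54823800 UMIs (unique molecular identifiers), the Ezh2-null library 11382 with 49755548, the het library 7512 with 57810497, the double-null library 6574 with 42281691 and the P2 library 5101 with 57598893. After filtering and removal of probable doublets, 9980, 10810, 7137, 6245 and 4835 cells remained in that order, with median depths of 4325.5, 3727, 6060, 5259 and 10148 UMIs per cell. The libraries also differed in the sex of their animals. Xist, expressed from the inactive X chromosome, had a UMI in 67.2% of control, 69.3% of Ezh2-null, 99.9% of het and 99.6% of P2 cells, but in 0.016% of double-null cells. Y-linked genes had a UMI in 21.9% of control, 16.7% of Ezh2-null and 50.2% of double-null cells, in 0.062% of P2 cells and in 0 of 7137 het cells. Sex therefore cannot be separated from genotype for the het and double-null libraries.

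Most cells of the control, Ezh2-null and double-null libraries were nephron progenitor-like, a class whose fixed markers include Six2, Cited1, Crym and Eya1. Progenitor-like cells made up 76.4% (75.6 to 77.2) of control cells, 88.9% (88.3 to 89.5) of Ezh2-null cells, 49.6% (48.4 to 50.8) of het cells and 89.3% of double-null cells. Committing nephron-like or more mature nephron-like cells, with Wnt4, Lhx1 and Jag1 among their markers, made up 4.68% (4.27 to 5.11) of control, 2.29% (2.01 to 2.58) of Ezh2-null, 4.79% (4.31 to 5.31) of het and 6.13% of double-null cells. Stroma-like cells, expressing Col1a1 and Col3a1, were 1.52%, 1.97%, 5.34% and 2.23% in the same order. Cells left without a name were 17.3% of control, 6.85% of Ezh2-null, 40.1% of het and 2.21% of double-null cells, and most of those in the het library lay in cluster 7, which held 30.6% of that library. With the unnamed clusters 5, 7, 9 and 16 counted as progenitors, the progenitor share became 93.7%, 95.6%, 88.6% and 91.3%. The het share moved to 75.2% with each library clustered on its own. Without the cell filter the control share was 46.9%, as a cluster with haemoglobin genes, Ocm and Cited1 among its leading genes took the erythroid name there. With doublets kept, a cluster with 3036 double-null cells, led by Cxcl1 and Egr4, stayed unnamed, and the double-null share was 43.1%. The progenitor-like shares therefore give no order of the genotypes. Among the E16.5 libraries, the nephron-like share was lowest in the Ezh2-null library under every setting run. The P2 library was mainly committing nephron-like (33.7%), proximal tubule-like (12.6%) and unnamed (49.6%), with only 7 progenitor-like cells in the joint clustering. Its nephron-like share of 48.9% was 12.7% and 63.7% at the 2 other clustering resolutions and 74.3% without the cell filter.

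**Figure D1:**
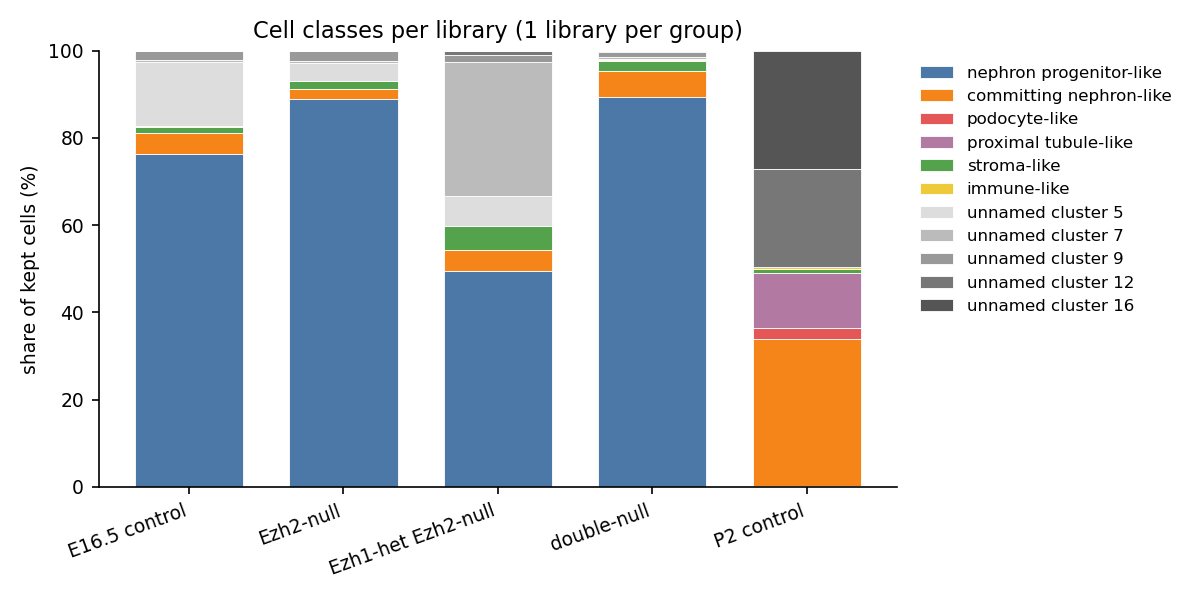
Share of kept cells (%, y axis) in each cell class for the 5 RNA libraries (x axis), 1 bar per library, with unnamed clusters in greys. Progenitor-like cells were 76.4% of control, 88.9% of Ezh2-null, 49.6% of het and 89.3% of double-null cells, and cluster 7 alone held 30.6% of the het library.

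Progenitor-like cells came largely from different clusters in different libraries. Clusters 4, 6 and 8 held the most in the control library and clusters 4, 6 and 1 in the Ezh2-null library, cluster 3 held 1646 of 3539 in the het library, and clusters 11 and 14 held 2336 and 3043 of 5578 in the double-null library. The leading genes of cluster 14 included Cxcl1, Egr4, Junb and Snai1. The values below compare all progenitor-like cells of a library as 1 sum, with 38132883 UMIs in the control, 40183900 in the Ezh2-null, 20766602 in the het and 34011872 in the double-null library.

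Ezh1 (ENSMUSG00000006920; chromosome 11, 101191115 to 101226463, mm10) stood at 12.5 CPM (11.4 to 13.7) in the control, 11.2 (10.2 to 12.3) in the Ezh2-null, 7.37 (6.25 to 8.63) in the het and 4.47 (3.79 to 5.24) in the double-null library. Ezh2 (ENSMUSG00000029687; chromosome 6, 47530274 to 47595270) stood at 156 CPM (152 to 160), 90.9 (88.0 to 93.9), 83.2 (79.3 to 87.2) and 131 (128 to 135) in the same order. The double-null level of Ezh2 was thus close to the control, at a log2 ratio of −0.24. It was 0.13 with doublets kept, where 2647 of the 2833 double-null progenitor-like cells left lay in 1 cluster led by cycle genes. Tags from the 3′ end of a transcript can lie outside the deleted part of a gene, so these levels check neither deletion. Of the PRC2 partners, Eed was at 72.4, 51.7, 42.7 and 33.5 CPM, and Suz12 at 43.2, 40.8, 31.8 and 22.9 CPM. Of the 11 PRC2 subunits, 1 was at least 1.5-fold lower in the Ezh2-null library, 2 in the het and 4 in the double-null library, with none that much higher. The medians of the list were −0.31, −0.39 and −0.23, so the median showed no order by Ezh1 dose, whereas Eed, Suz12 and the number of lower subunits did. In stroma-like cells the medians were −0.225, −0.32 and −0.27, so the lower level was not particular to progenitor-like cells. Six2, the progenitor self-renewal factor, stood at 101, 188, 101 and 58.7 CPM, and Cited1, a marker of the least committed progenitors, at 131, 139, 118 and 77.2 CPM.

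**Figure D2:**
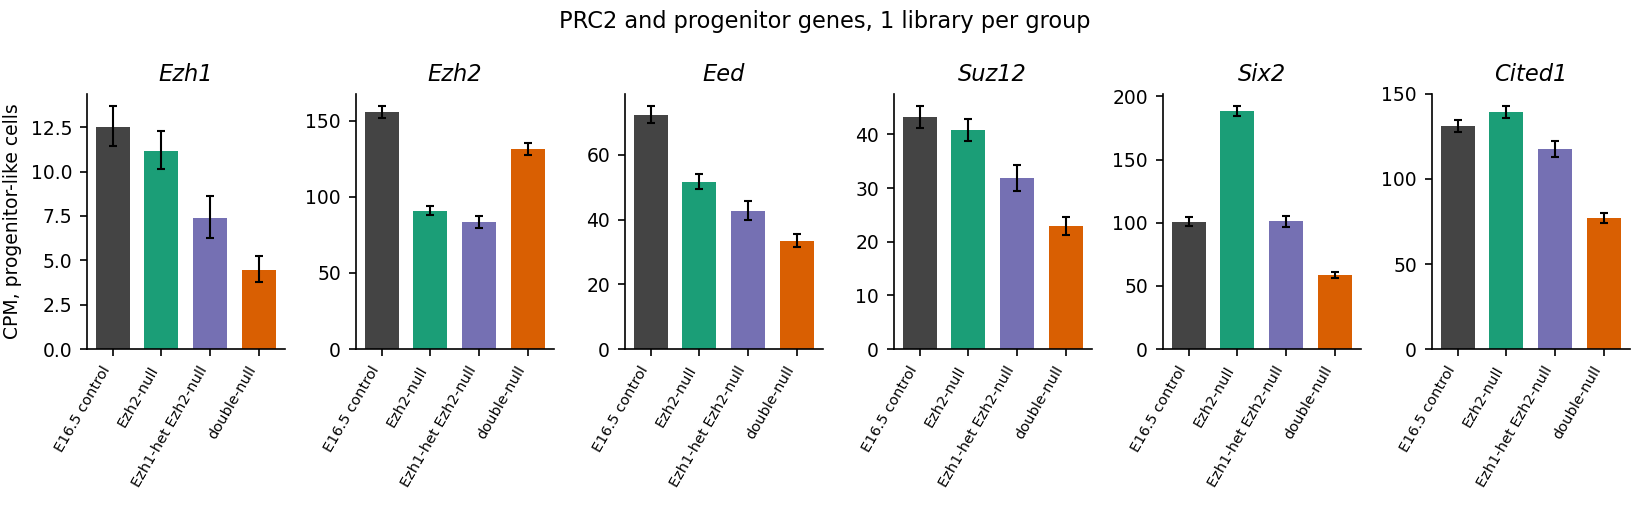
CPM (y axis) of Ezh1, Ezh2, Eed, Suz12, Six2 and Cited1 summed over progenitor-like cells of the 4 E16.5 libraries, with exact Poisson 95% intervals for counting error. Eed went from 72.4 CPM in the control to 33.5 in the double-null library, while Ezh2 was at 156 and 131.

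The comparison of the double-null library with the control asks what progenitors labelled as lacking both methyltransferase genes express. Transcription factors of other lineages, with few or no counts in control progenitors, were found in the double-null library. Of 99 fixed developmental regulators, 8 had at least 10 counts in control progenitor-like cells, 12 in Ezh2-null, 16 in het and 49 in double-null cells. Over all filtered cells these counts were 18, 19, 38 and 55, and with the unnamed clusters added the het count was 28. Thinned to 1 total of 20766602 UMIs, the counts of regulators were 7, 9, 16 and 38. Of 91 regulators with under 10 control counts, 41 (45.1%) reached 10 in the double-null library, against 542 of 14055 other genes (3.86%). The same shares were 4.396% and 2.41% for the Ezh2-null library, and 8.79% and 0.711% for the het library. These counts of regulators were chosen as a measure after the data were seen.

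Gata2, a blood and endothelial factor, had 5 counts in the control, 7 in the Ezh2-null, 21 in the het and 237 in the double-null library, a double-null ratio of 53.1 (22.5 to 165). Msx1 was at 3 counts in the control and 151 in the double-null library, and Tbx3 at 3 and 124. Factors with 0 control counts included Dlx2 (71 double-null counts, at least 26.5-fold higher over a 3-count floor), Nkx2-1 of the lung and thyroid (54 counts, at least 20.2-fold) and En1 (51 counts, at least 19.1-fold). Regulators already present in the control went both ways: Msx2 was at 1.28 and 14.0 CPM, and Prrx1 of limb and craniofacial mesenchyme at 5.56 and 27.0 CPM, whereas Foxd2 was at 39.5 and 28.5 CPM and Prrx2 at 12.7 and 3.15 CPM. Among the 49 measured regulators, 7 were at least 1.5-fold higher on the log2(CPM + 5) scale and 2 lower, Six3 (−1.12) among them. Their median of 0.23 lay above all 10000 matched random lists, and was 0.91 with a pseudocount of 1 CPM and 0.062 with 20 CPM. Members with few control counts were measured through their double-null counts, which raises this median. Over all 99 regulators with no count filter it was 0.050, with 78 above the control, 4 below it and 17 without a count in either library. In stroma-like cells of the same libraries, the 10 regulators that could be measured had a median of −0.48, against 0.14 for the same 10 in progenitor-like cells. The 12 measured stroma markers had a median of −0.0044 in progenitor-like cells, with Acta2 (1.10), Tagln (0.92) and Meis1 (0.90) higher and Col1a1 (−0.59) lower. Markers of some other cell types were higher there, with medians of 0.64 for erythroid, 0.24 for ureteric epithelium and 0.16 for loop and distal tubule markers. The erythroid value rests on 3 haemoglobin genes. With the unnamed clusters added, its median was 1.27 in the Ezh2-null, 2.01 in the het and 0.62 in the double-null library. None of the 6 measured loop and distal tubule markers was past 1.5-fold.

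**Figure D3:**
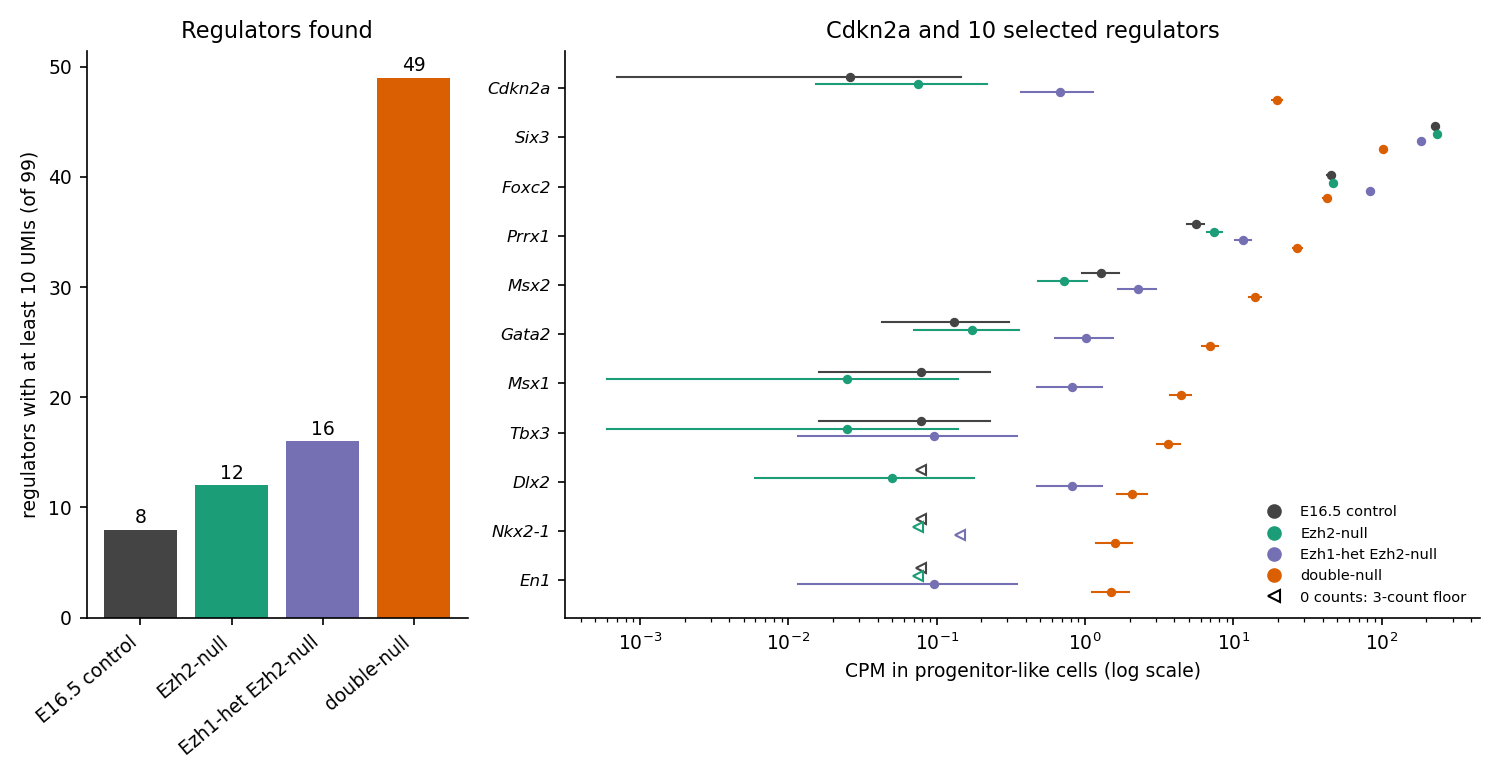
Left, number of the 99 developmental regulators with at least 10 UMIs in progenitor-like cells of each E16.5 library: 8, 12, 16 and 49. Right, CPM on a log scale of Cdkn2a and 10 selected regulators, with exact Poisson 95% intervals and open triangles for the 3-count floor of libraries with 0 counts.

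Cdkn2a (ENSMUSG00000044303; chromosome 4, 89274473 to 89294619), a cell cycle inhibitor gene and a known Polycomb target, had 1 count in control progenitor-like cells, 3 in Ezh2-null cells and 667 in double-null cells. The double-null level was 19.6 CPM (18.2 to 21.2), a ratio to control of 748 with a counting interval of 134 to 29581. The neighbouring Cdkn2b had 94 counts against 3, a ratio of 35.1 (11.7 to 173). A Cdkn2a UMI was found in 10.0% (9.26 to 10.9) of double-null progenitor-like cells and in 28.7% (24.2 to 33.5) of committing nephron-like cells, at median depths of 5126.5 and 7040 UMIs. In the stroma-like cells of that library the share was 4.32% (1.60 to 9.16) at a median of 6302 UMIs, and in control progenitor-like cells 0.0131%. The het library lay between, with a Cdkn2a UMI in 0.396% (0.216 to 0.663) of progenitor-like and 7.02% (4.55 to 10.3) of committing nephron-like cells, at medians of 4729 and 8478.5 UMIs. Cdkn1c, an imprinted inhibitor of the same process, went the other way, at 226 and 75.7 CPM (log2 ratio −1.52). Across the 7 measured cyclin-dependent kinase inhibitors 2 were at least 1.5-fold higher and 1 lower, with a median of 0.18.

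Commitment markers were higher within double-null progenitor-like cells and several progenitor markers lower. Osr2 (1.91), Pax8 (1.23), Wnt4 (1.14) and Lhx1 (0.95) led the 6 of 13 committing nephron markers that were at least 1.5-fold higher. The median of that list was 0.50, above all matched random lists. The unnamed cluster 5, with Notum and Wnt4 among its leading genes, held 1467 control and 23 double-null cells and was left out of these values. With the unnamed clusters added the median was 0.43, with 4 past 1.5-fold, Wnt4 at 0.79 and Lhx1 at 0.83. Over all filtered cells it was 0.28, with 3 past 1.5-fold, Wnt4 at 0.71 and Lhx1 at 0.42. Of 14 progenitor markers 5 were at least 1.5-fold lower, led by Eya1 (−1.39), Uncx (−1.35), Meox1 (−0.91) and Six2 (−0.73), while the median was −0.15 (percentile 15.5). Wnt target genes had a median of 0.24, with Sp5 (1.17), Lef1 (0.84) and Ccnd1 (0.74) the 3 members past 1.5-fold. With the unnamed clusters added, Lef1 stood at 0.54 and Ccnd1 at 0.52, both under 1.5-fold, so these values depended on the cells named. Notch pathway genes had a median of 0.45, with Hey1 (1.64), Hes1 (1.31) and Heyl (0.88) among 5 higher members. Notch2 (−0.90) was the single lower member, at 0.47 without clusters 0 and 2, which Notch2 helps define. In stroma-like cells the 7 measured Notch pathway genes had a median of 0.72, against 0.61 for the same genes in progenitor-like cells, with 6 in the same direction in both. The 7 measured Wnt target genes stood at −0.071 in stroma-like cells against 0.24.

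Hox genes of paralog groups 1 to 9 were lower in the double-null library. Of these, 11 of 27 genes were at least 1.5-fold lower and 0 higher, with a median of −0.34, and Hoxb8 (−1.14), Hoxc9 (−1.04), Hoxc8 (−0.91) and Hoxb4 (−0.90) had the lowest ratios. The 21 members measured in stroma-like cells had a median of −0.53 there and of −0.60 in progenitor-like cells. Groups 10 to 13 were divided, with Hoxa10 (−1.34) and Hoxd11 (−1.02) lower and Hoxc11 (0.91) and Hoxd13 higher, the last at 156 counts against 4.

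The genes with the highest double-null ratios were Snai1 (3.14), a repressor of epithelial genes, the stress factors Atf3 (2.47) and Nr4a1 (2.19), Nfkbia (2.07), Id1 (2.02), Nfib (1.90), Bcl11a (1.89), the imprinted RNA Meg3 (1.88), Stat3 (1.85) and Cxcl1 (1.73). Snai1, Junb and Cxcl1 were also among the leading genes of cluster 14. Dissociation stress genes had a median of 0.37, with 7 of 15 at least 1.5-fold higher, including Junb (1.61) and Hspa1a (1.31). The 14 measured in stroma-like cells had a median of 0.65 there and of 0.62 in progenitor-like cells. The lowest ratios belonged to the splicing factor Srsf2 (−4.08), Jund (−3.43), Ptov1 (−3.36), Akirin2 (−3.27), Mtch1 (−3.21), Chic2 (−3.09), Rnf187 (−2.97), Dapk3 (−2.96), the mRNA export factor Alyref (−2.84) and Taf10 (−2.76). These 10 genes had a median of −3.03 in stroma-like cells and of −3.63 in the P2 control over the E16.5 control. p53 target genes, led by Pmaip1 (0.97), had a median of 0.18, but one of 0.0033 with the unnamed clusters added.

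**Figure D4:**
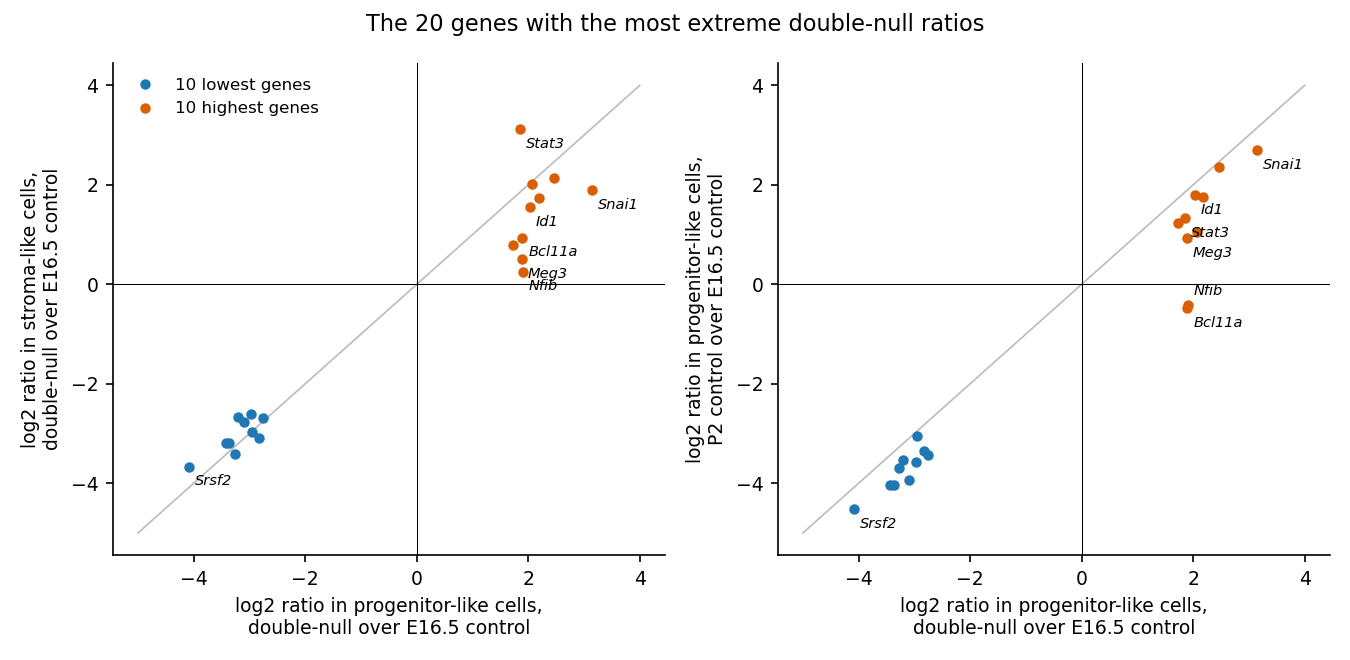
The 10 highest and 10 lowest genes of the double-null library, with the log2 ratio in progenitor-like cells (x axis) against that in stroma-like cells (left, y axis) and against the P2 over E16.5 control ratio (right, y axis). The lowest genes lie near the diagonal in both panels, with Srsf2 at −4.08, −3.67 and −4.52, while Nfib is at 1.90 in progenitor-like and 0.25 in stroma-like cells.

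The het library, with 1 Ezh1 allele left, shared part of this profile. Snai1 (2.47) again led, followed by Snhg9 (1.59), the cyclin Ccnd2 (1.47), Id1 (1.21), Rab26os (1.19), Hey1 (1.18) and Hk2 (1.09). Among the lowest ratios were those of Hist1h2ap (−3.09), Gstp1 (−2.03), Ccdc85b (−1.69) and Pgk1 (−1.52). The library's 10 highest and 10 lowest genes had medians of 0.97 and −1.06 in stroma-like cells, all 20 in the same direction. Notch pathway genes had a median of 0.47 with 4 of 10 at least 1.5-fold higher, Nrarp (1.02) and Hes1 (0.82) among them. The 8 measured in stroma-like cells had a median of 0.46 there and of 0.57 in progenitor-like cells. The 20 measured developmental regulators had a median of 0.13, above all matched random lists but 0.00 with no count filter, with Foxc2 (0.82) and Prrx1 (0.66) the 2 past 1.5-fold. Cluster 7, left out of these values with 2184 het cells, had the regulators Prrx1 and Msx2 among its leading genes. With the unnamed clusters added the median of the measured regulators was 0.096. Stroma markers were higher as well: their median in progenitor-like cells was 0.28, with Foxd1 (0.81), Tagln (0.81) and Acta2 (0.81) higher. Six2 was at its control level (log2 ratio 0.00), and Eya1 (−0.82) was lower.

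G2 and M phase genes were lower in het progenitor-like cells, with 29 of 52 at least 1.5-fold lower and a median of −0.67, among them Nusap1 (−1.03), Cdc20 (−1.01) and Aurka (−1.01). This difference rested on which cells carried the progenitor name, since the median became −0.08 once the unnamed clusters, including cluster 7, were added, and S phase genes went from −0.30 to 0.02.

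The Ezh2-null library, with both Ezh1 alleles intact, stood closest to the control in the groups that set the double-null library apart. The 14 measured developmental regulators had a median of 0.046, none past 1.5-fold, and Hox groups 1 to 9 a median of −0.010. Its highest ratios were those of the non-coding RNA Snhg9 (1.95), Nme2 (1.63), Wdr89 (1.61), Phpt1 (1.51), Erdr1 (1.503) and the neurotrophin receptor Ngfr (1.32). Gt(ROSA)26Sor (−2.94), the transcript of the locus commonly used for reporter knock-ins, was lowest, followed by Ccdc85b (−1.46), Uqcrb (−1.44) and Hist1h2ap (−1.28). Six2 was 1.87-fold higher (1.80 to 1.94), the reverse of the double-null library. Hes1 (−1.11), Hey1 (−0.61) and Jag1 (−0.54) were lower, also opposite to the double-null and het libraries for Hes1 and Hey1, and the Notch list had a median of −0.13. Glycolysis genes had a median of 0.36, above all matched random lists, with Aldoa (0.80), Ldha (0.74) and Slc16a3 (0.64) among 4 of 16 higher members and Eno1 (−0.88) lower. The glycolysis median in stroma-like cells was 0.27, and the library's 10 highest and 10 lowest genes had stroma-like medians of 1.25 and −1.19. Heterochronic genes, a list of the Lin28, Hmga and Igf2bp families, had a median of 0.30, with Igf2bp1 at 0.54 and Hmga2 at 0.36.

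Some genes departed from the control in the same direction in all 3 mutant libraries. Above it were Bcl11a (1.504, 1.72 and 1.89 in the Ezh2-null, het and double-null libraries), Ccnd2 (1.08, 1.47 and 1.47), the transcription factors Nfia (1.014, 0.999 and 1.51) and Nfib (0.85, 1.04 and 1.90), Saa1, Saraf, Sel1l3, Mt1, Pcp4 and Ngfr. Below it were Hist1h2ap (−1.28, −3.09 and −1.97), Gstp1 (−1.12, −2.03 and −1.99), Ccdc85b, Hmgn2, Dynlt1f, Lsm7, Mid1, the cartilage collagen Col2a1 (−0.85, −0.93 and −0.96), Impact and Glo1. Of 5344 genes open to naming, 9 were at least 1.5-fold above the control in all 3 libraries and 27 below. Draws of unchanged libraries gave 0 and 0, and independent lists would give 0.0238 and 0.781. The draws hold counting error alone and all 3 ratios share 1 control library, so part of the excess may come from that library. With no bound on size, 510 genes were above the control in all 3 libraries and 1728 below. The draws gave means of 1251 and 1253, and independent lists would give 232 and 1328. Shared direction thus leaned downward, with fewer genes above than in the draws. Counts of genes with near-identical copies or overlapping neighbours, such as Hist1h2ap, Gstp1, Nme2, Erdr1 and Tpm3-rs7, are uncertain.

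**Figure D5:**
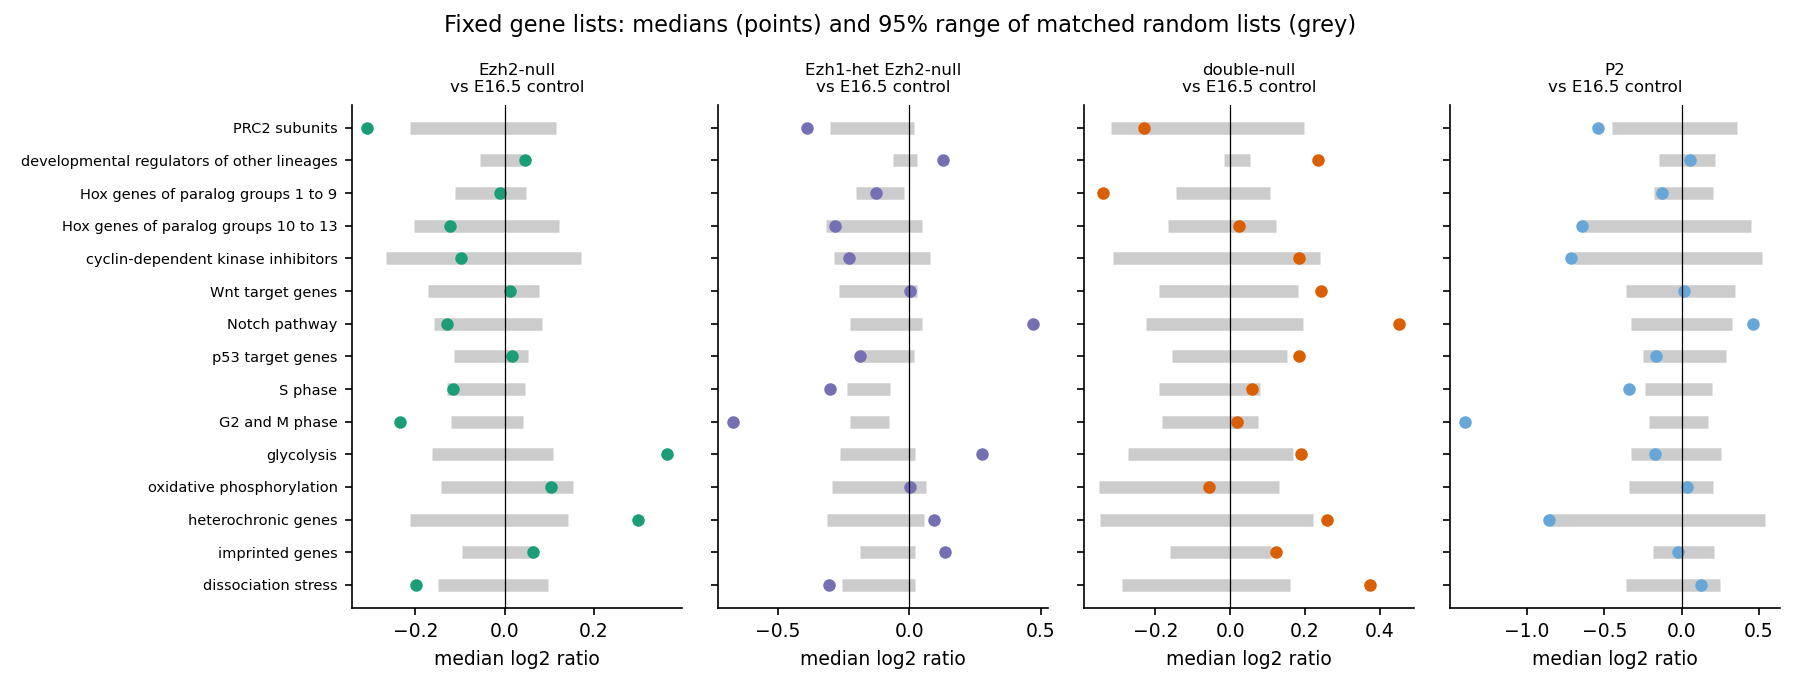
Median log2 ratio (x axis) of each fixed gene list (y axis) against the E16.5 control in the Ezh2-null, het, double-null and P2 libraries, with the 95% range of 10000 expression-matched random lists in grey. Developmental regulators stood at 0.046, 0.13 and 0.23 in the 3 mutants, and G2 and M phase genes at −1.40 in the P2 library, where a cluster of cycling cells is left out.

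Across decreasing Ezh1 dose on the Ezh2-null background, from both alleles through 1 to none, genes were ranked only if both steps were at least 0.3 in the same direction. This rule leaves out genes that changed at 1 step only. Among the ranked genes, the highest double-null ratios over the Ezh2-null library were those of Snai1 (3.22), Nfkbia (2.55), the stress gene Gadd45b (2.51), Hes1 (2.41) and Id1 (2.403). Srsf2 (−3.81), Ptov1 (−3.48), Rnf187 (−3.18), the linker histone H1fx (−3.16) and Suds3 (−2.69) had the lowest among them. In stroma-like cells the ratios of the first 5 were 3.104, 1.78, 2.19, 2.22 and 1.91 and those of the last 5 −3.62, −3.42, −2.74, −3.57 and −2.77, so neither set was particular to progenitor-like cells. At P2 over the E16.5 control, the first 5 stood at 2.69, 1.05, 3.99, 0.20 and 1.79. The last 5 were low there, at −4.52, −4.03, −3.56, −3.39 and −2.84. Six2 was lower by a log2 ratio of −1.60 and Ezh1 of −0.77, while Ezh2 was higher (0.51). The median of the regulators between these libraries was 0.23, that of the Notch list 0.65 and that of the stress list 0.72, each above all matched random lists.

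The P2 control asks how the same genotype differs shortly before nephron formation ends. Its progenitor-like cells were taken from clusters made within each library, 863 at P2 and 8455 in the E16.5 control, a choice made after the joint clustering was seen. A further P2 cluster of 553 cells, led by cycle genes such as Pbk, Spc25 and Aurkb with Six2 and Eya1, stayed unnamed and was left out, while cycling clusters of the control were named and used. At P2, Cited1 (−2.30), Uncx (−2.46), Meox1 (−2.07) and Six2 (−1.25) were lower, with 11 of 14 progenitor markers at least 1.5-fold lower and a median of −1.46. With that cluster added, a setting chosen after the data were seen, the median was −1.34 and Six2 stood at −1.07. Tmem100, also among the 14 progenitor markers, was the 1 at least 1.5-fold higher, at 3.34 without that cluster. Committing nephron markers were higher, 7 of 12 past 1.5-fold with a median of 1.36, led by Lhx1 (3.32), Ccnd1 (2.91), Wnt4 (2.68) and Osr2 (2.38). The Notch genes Hey1 (3.01), Jag1 (2.0003) and Notch1 (1.92) were higher. The growth regulators Igf2 (−3.71) and Cdkn1c (−3.41), both imprinted, and the heterochronic gene Hmga2 (−1.67) were lower, as were the PRC2 genes Eed (−1.33), Suz12 (−1.28) and Ezh2 (−1.12), although Ezh2 was at −0.36 with the cycling cluster added. Highest were Pmp22 (4.51), Gadd45b (3.99), Npy (3.67), the tubule cadherin Cdh6 (3.62), Lbp (3.47) and Tmem100 (3.34), with the contractile stroma markers Acta2 (3.54) and Tagln (2.99). The lowest ratios included Srsf2 (−4.52), Robo2 (−4.04), Ptov1 (−4.03), Jund (−4.03) and Chic2 (−3.94), 4 of which were also among the lowest of the double-null library.

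The level of cycle genes at P2 depended on the cells named. Without the cycling cluster, G2 and M phase genes were lower for 49 of 52 members, with a median of −1.40, led by Top2a (−2.91) and Ube2c (−2.77), and S phase genes had a median of −0.34. With it, the medians were 0.078 and 0.30, so no direction is drawn for either list. Over all filtered cells, 48.9% of which were nephron-like at P2, only 4 of the G2 and M phase genes were at least 1.5-fold lower and 4 were higher, with Aurkb, Nusap1 and E2f8 above the control. The P2 library was counted on another gene annotation, so genes at or near 0 there, such as Fdx1l (0 against 2995 counts), Scand1, Srp54b and Sept2, are uncertain.

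Thinned to 2000 UMIs per cell, a UMI of Mki67 or Top2a was found in 25.1% (24.1 to 26.1) of control, 24.03% (23.2 to 24.9) of Ezh2-null, 14.8% (13.6 to 15.99) of het and 27.4% (26.2 to 28.6) of double-null progenitor-like cells. Without thinning the shares were 39.1%, 35.7%, 28.1% and 44.7%. Adding the unnamed clusters brought the het share to 24.6%, and keeping doublets the double-null share to 54.1%, over cells mostly of the 1 cluster led by cycle genes. Thinning left out 42 control and 532 Ezh2-null cells. In progenitor-like cells of each library's own clusters the thinned share was 23.1% (22.2 to 24.1) at E16.5 and 4.29% (3.04 to 5.86) at P2, but 22.2% (20.04 to 24.4) at P2 with the cycling cluster added. In P2 podocyte-like cells, which do not divide, it was 1.65% (0.201 to 5.84) of 121 cells.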

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

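The free RNA test of Cdkn2a by committing nephron-like cells, the P2 test of the lowest genes and the depth test over all regulators were chosen after their results were seen, and the other tests before. A further test, of stromal cells among the progenitor-like cells by the median of 12 stroma markers (−0.0044), decided nothing.

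The 10 genes lowest in double-null progenitor-like cells, Srsf2, Jund and Ptov1 among them, were weighed first. A difference between these libraries that touches every cell type predicted a median below −1.5 in stroma-like cells, and the median was −3.03 (−3.30 to −2.69 over genes), with all 10 genes lower. Loss of Ezh1 in stroma-like cells, which the labels allow, could give the same, so this value cannot separate it from a difference between libraries. The P2 control, with no Ezh mutation by its label, gave a median of −3.63 (−4.03 to −3.43 over genes) against the E16.5 control. Ezh2 was also lower at P2 (−1.12, or −0.36 with a cluster of cycling cells added), but a lower Ezh2 alone did not go with these losses, as the 10 genes had a median of −0.0036 in the Ezh2-null library, and loss of both genes stays open for the double-null library alone, as the lower level at P2 can have another cause. The loss of these transcripts is thus consistent with a difference in how the libraries were made or sequenced, and no biological meaning should be drawn from it without more libraries.

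The 10 highest double-null genes, led by Snai1, Atf3 and Nr4a1, had a median of 1.96 (1.79 to 2.32 over genes) thinned to 2000 UMIs per cell. Thinning keeps each gene's expected share of UMIs, so this value lay near the unthinned one by construction and decides nothing on depth. In stroma-like cells their median was 1.65 (0.722 to 2.03 over genes), all 10 genes higher. That interval reaches below the bound of 1 set for a difference touching every cell type, so the set leaves it open. In the P2 control over the E16.5 control, a value looked at afterwards, their median was 1.28, with Snai1 at 2.69 and Bcl11a at −0.48, so part of the set was high without an Ezh mutation. Stat3 (3.11), Atf3 (2.13) and Nfkbia (2.03) were as high in stroma-like cells, whereas Nfib (0.25) and Meg3 (0.50) were not. Depth, stress during dissociation, sex and genotype all remain open, as 1 library carries them together.

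Cdkn2a and the developmental regulators were weighed as the third pattern. Free RNA as the only source of Cdkn2a would give every cell type a like level, but committing nephron-like cells held 2.62 times (2.18 to 3.12) the progenitor-like CPM. Free RNA from those cells could still supply part of the progenitor-like counts, which this value cannot decide. The test written beforehand asked for an upper limit below 0.5 for stroma-like over progenitor-like cells and was not met, at 0.327 (0.119 to 0.714). Depth as the source of the regulators' median is argued against by a median of 0.36 after thinning, outside the −0.0518 to 0.0964 of matched random lists, and, since the count filter raises it, by one of 0.051 over all 99 regulators thinned with no filter, above all 10000 matched random lists, and male cells as the source of Cdkn2a by 0 counts in 1290 male control cells, an upper limit of 0.595 CPM against 18.8 CPM in double-null cells with a Y-linked UMI. Release of Polycomb targets without Ezh1 and Ezh2 is a candidate explanation. It remains a hypothesis from 1 library that no test here separates from depth per cell, free RNA, animal, litter, handling or admixed cells.

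Haemoglobin transcripts, left out of the named genes and of the 15 lists but counted as erythroid markers, were above the control in all kept cells of the mutant libraries: 32.8 CPM in the Ezh2-null, 64.3 CPM in the het and 7.70 CPM in the double-null library, against 0.239 CPM in the control.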

How the results depend on the processing

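The alternatives that add the unnamed clusters to the progenitor-like class, that leave out the clusters led by Notch2, that use cluster 16 for P2 or add the cycling cluster to it, that drop the cell filter and keep doublets together, and all those of the count of regulators were chosen after the data were seen, and the others before. No paired analysis was possible because each group has 1 library. Depth, 1 library per group and rebuilt cell names limit all values. Intervals cover counting error only, or the spread of the chosen genes where given over genes or members. Small sets such as the 139 stroma-like double-null cells limit what a second cell type can show. Of 319 named-gene ratios past 1.5-fold, 319 kept their sign under TMM, DESeq2, pseudocounts of 1 and 20 CPM, thinning and each library's own gene set. These settings tested the signs little. A pseudocount cannot change a sign, thinning keeps each gene's expected share, and TMM, DESeq2 and the gene set only rescale whole libraries. Changes of cells can change a sign, and 316 kept it over all filtered cells. Of 247 that the cell set without the Notch2-led clusters could test, 246 kept it. Among all named-gene values 3560 stayed within their counting interval, 1498 left it and 9 were counted as changed in sign. Gene list medians stayed within a bootstrap interval over members 819 times, left it 65 times and were counted as changed in sign 1 time. A change of sign was counted only for values past 1.5-fold whose interval excluded 0. Smaller values that changed sign, such as the P2 S phase median with the cycling cluster added, are counted as having stayed or left. Setting no low-count filter and using each library's own gene set moved 0 of 429 named-gene ratios, the first by construction. For the values below the cause was not tested, except where cells or names are given and that a larger pseudocount and unmeasured list members draw a median to 0 by construction.

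Over all filtered cells the P2 ratios changed sign for Aurkb (0.31), Nusap1 (0.083) and E2f8 (0.28), as did Notch2 in the double-null library without the Notch2-led clusters (0.47). With the P2 cluster of cycling cells added, the P2 ratios of Aurkb (0.53), Nusap1 (0.24), E2f8 (0.21), Rrm2 (0.12) and Cdkn2d (0.064) and the G2 and M phase median (0.078) changed sign, and the P2 cycling share was 22.2%. Of 72 P2 ratios past 1.5-fold, 67 kept their sign there. These moves follow from the cells that setting adds.

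Without a cell filter the progenitor-like share was 46.9% in the control, 53.9% in the Ezh2-null, 68.4% in the het and 88.2% in the double-null library, and the nephron-like share 7.71% in the control, 4.51% in the Ezh2-null, 13.2% in the het and 74.3% in the P2 library. These moves are changes of cluster and name rather than of cells, as 9999 control cells were clustered in place of 9980, and a cluster with haemoglobin genes, Ocm and Cited1 among its leading genes took the erythroid name with 24.9% of control and 30.2% of Ezh2-null cells. With doublets kept as well, progenitor-like shares were 61.6%, 62.3%, 48.2% and 88.5% from the control to the double-null library, nephron-like shares 3.70%, 1.73% and 3.58% from the control to the het and 13.1% in the P2 library, and that name took 25.98% of control and 28.4% of Ezh2-null cells. With the stricter filter the progenitor-like shares were 71.4% (control), 81.8% (Ezh2-null) and 76.3% (het), and the nephron-like shares 5.45%, 3.47%, 6.24%, 7.88% (double-null) and 32.8% (P2). At resolution 0.5 the progenitor-like shares were 91.7%, 93.6% and 87.0% in the control, Ezh2-null and het libraries, and the P2 nephron-like share 12.7%. At resolution 2 they were 79.8%, 86.8% and 74.0%, with nephron-like shares of 3.90% (control) and 63.7% (P2). With each library clustered on its own, progenitor-like shares were 84.7% (control), 81.5% (Ezh2-null), 75.2% (het), 69.4% (double-null) and 17.8% (P2), nephron-like shares 5.49% (control), 3.09% (Ezh2-null), 6.87% (double-null) and 20.04% (P2), and Ezh2 ratios −0.65 (het) and −0.66 (Ezh2-null). With doublets kept, progenitor-like shares were 48.3% (het) and 43.1% (double-null), nephron-like shares 3.58% (control), 1.76% (Ezh2-null), 3.91% (het) and 54.1% (P2), cycling shares 22.6% (control), 23.0% (Ezh2-null) and 54.1% (double-null), and the double-null Ezh2 ratio 0.13. The double-null values there are over 2833 progenitor-like cells, 2647 of them in 1 cluster led by cycle genes, as a cluster with 3036 double-null cells went unnamed. With the unnamed clusters added, progenitor-like shares were 93.7%, 95.6%, 88.6%, 91.3% and 27.3% from the control to P2, cycling shares 21.4% (control), 23.0% (Ezh2-null), 24.6% (het) and 2.28% (P2), Ezh2 ratios −0.54 (het), −0.69 (Ezh2-null) and −0.16 (double-null), and 28 regulators had 10 counts in the het library.

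A pseudocount of 1 CPM gave Ezh1 ratios of −0.69 (het) and −1.31 (double-null) and regulator medians of 0.13 (Ezh2-null), 0.49 (het) and 0.91 (double-null). With 20 CPM the Ezh1 ratios were −0.25 and −0.41, the Ezh2 ratios −0.77 (het) and −0.66 (Ezh2-null), and the regulator medians 0.012, 0.033 and 0.062. With no low-count filter those medians were 0.00 (Ezh2-null), 0.00 (het) and 0.050 (double-null). The het Ezh2 ratio was −0.74 under TMM, −0.73 under DESeq2 and −0.97 without the Notch2-led clusters. Over all filtered cells it was −0.54, the double-null Ezh2 ratio −0.18, the Ezh2-null regulator median 0.013, and 18 (control), 19 (Ezh2-null) and 38 (het) regulators had 10 counts, against 55 in the double-null library. Thinned to 2000 UMIs per cell, Ezh2 ratios were −0.77 (het), −0.68 (Ezh2-null) and −0.14 (double-null). The cycling share from the control to P2 was 52.8%, 55.9%, 29.1%, 49.2% and 7.95% at 4000 UMIs, over only the 4326, 3960, 2548, 4039 and 855 cells that deep, and 39.1%, 35.7%, 28.1%, 44.7% and 14.8% without thinning.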

Other observations

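Oxidative phosphorylation genes stood near the control in progenitor-like cells of every mutant, with medians of 0.10 in the Ezh2-null, 0.0014 in the het and −0.056 in the double-null library, and 0 of 17 members at least 1.5-fold higher. Single members departed, such as Uqcrb (−1.44) in the Ezh2-null library and Ndufb7 (−0.74) in the double-null library. Imprinted genes went both ways in the double-null library, with 4 of 19 higher, Meg3 (1.88) and the transmembrane protein gene Dlk1 (0.92) among them, and 4 lower, including Cdkn1c (−1.52) and Impact (−0.93). Their median was 0.12 there, 0.13 in the het and 0.063 in the Ezh2-null library. Heterochronic genes had a double-null median of 0.26, with the RNA-binding Igf2bp3 (0.61) higher and Hmga2 (−0.52) lower. Glycolysis genes had a double-null median of 0.19 and a het median of 0.28, with the hexokinase Hk2 higher in both (0.84 and 1.09) and Pgk1 lower in both (−1.496 and −1.52). G2 and M phase genes had a double-null median of 0.019 and S phase genes one of 0.057, which became 0.67 and 0.50 with doublets kept, where most progenitor-like cells left lay in 1 cluster led by cycle genes.

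Markers of other cell types gave the following medians in progenitor-like cells. Ureteric epithelium markers stood at −0.039 in the Ezh2-null, 0.086 in the het and 0.24 in the double-null library, with the keratin Krt18 at 0.96 in the het and 1.14 in the double-null library. Podocyte markers were at −0.017, proximal tubule markers at 0.17, loop and distal tubule markers at 0.16, endothelium markers at 0.013 and neural markers at 0.096 in the double-null library. Erythroid markers, all haemoglobin genes, were at 0.64 there, and immune markers, measured over all filtered cells, at 0.041. In the Ezh2-null library endothelium markers stood at 0.19, above the range of matched random lists, and podocyte markers at −0.084, below theirs. Loop and distal tubule markers stood at 0.17 in the het library, above their range. Committing nephron markers stood at −0.076 in the Ezh2-null and 0.15 in the het library. Progenitor markers stood at 0.081 and −0.13 in those libraries.

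Stroma-like cells gave a second view of each library. In the double-null library p53 target genes had a median of −0.48 in stroma-like cells against 0.20 for the same 10 genes in progenitor-like cells. In the het library the G2 and M phase genes stood at 0.20 in stroma-like cells and at −0.67 in progenitor-like cells. The progenitor-like medians of both lists depended on whether the unnamed clusters were added, as given above, so neither contrast is one of cell type alone.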
